A study of Mus musculus with 2 samples.

How the data were processed

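The series holds 2 samples of MOS-J, a mouse osteosarcoma cell line. One carries a control vector (group control) and the other the human DKK1 gene (group DKK1). Total RNA from cell pellets was labelled with biotin by a 3' in vitro transcription protocol, starting from 500 ng, and each sample was hybridised to 1 Affymetrix mouse expression array, per the labels' protocols. The labels call both vectors lentiviral, while the treatment protocol gives a lentiviral route with G418-selected clones and also a plasmid route with blasticidin selection, followed by labelling with a red fluorescent protein and cell sorting. Which of these steps the profiled cells went through is not given in the sources used here. The series title names an osteochondrosarcoma, and the sample labels an osteosarcoma.

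The values are intensity values on a linear scale, deposited as 1 signal per probe set for 45101 probe sets. They were summarised with MAS5, per the submitters' processing notes, and the version and settings are not given in the sources used here. MAS5 summarises the perfect-match and mismatch probes of a probe set into 1 signal and scales each array on its own. Computed from the values, the mean signal without the highest and lowest 2% was 500 on both arrays, so the arrays were scaled to the same trimmed mean and not matched in any other way. This scaling fixes the average level of each array and so cannot show a shift shared by all genes. MAS5 signals of dim probe sets are noisy, and the table used here carries no detection calls.

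Gene symbols came from the platform annotation of the array's probe sets and were updated by gene ID through a RefSeq table of assembly GRCm38.p6. Of the 45101 probe sets, 64 are control probe sets, 34958 have 1 gene symbol, 932 have several symbols and 9160 are unnamed here, where 13 of the control probe sets also count among those with symbols. Of those with 1 symbol, 34754 matched by gene ID and none changed its symbol. They cover 18194 genes. The array's own genome build is not given in the sources used here, so no coordinates are printed, and the RefSeq table served for names, chromosomes and gene order alone.

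With 1 array per group there are no replicates, no test across genes and no p-values. Each difference compares these 2 arrays and has no replicate check, and the number of arrays limits the precision. No scan date or batch was given in the sources used here, and batch and group cannot be told apart with 1 array each. The differences were log2(signal + 16.6) of the DKK1 array minus that of the control array, where 16.6 is the 25th percentile of all signals on both arrays. This pseudocount moves the differences of dim genes towards 0, compared with none. A probe set counted as measured where the mean of its 2 signals reached 71.3, the median of those means over all probe sets. That left 22499 measured probe sets, of which 19360 carry 1 symbol, for 11058 genes. The difference of a gene is the mean over its measured probe sets with 1 symbol. A gene was called higher or lower where its difference was at least 1 on the log2 scale (2-fold) and all its measured probe sets had that sign. Of the measured genes, 4978 have at least 2 measured probe sets, and the pooled SD between probe sets of 1 gene was 0.46 on the log2 scale. That SD describes technical agreement within arrays, not the spread between cultures.

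A set of 29 gene lists with 921 entries was written from textbook knowledge before the data were examined, along with the calling rule, the filter and the naming rule. For each list, the median difference of its measured genes was set against 10000 random lists of the same size, matched on mean log2 signal in 20 bins. A list was said to stand apart where its median lay below the 2.5th or above the 97.5th percentile of the random medians, which with 29 independent lists would happen 1.45 times by chance. The genes of a list are not independent of each other, so this percentile describes these 2 arrays and is not a test of DKK1. List entries under older symbols were matched through the synonyms of the RefSeq table. This matching was added after the list values had been seen. It brought 1 more gene into the glycolysis list and 2 into the chaperone list, and moved their medians little.

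The genes named are the 10 highest and the 10 lowest among called genes. To these were added the 5 highest and 5 lowest called genes with at least 2 measured probe sets each 2-fold or more in the same direction, leaving out those already named. From each list the rule took up to 3 called members with the largest differences, and for a list standing apart with few called members its 2 members with the largest difference in the list's direction. Dkk1, Aldh1a1, Axin2, Runx2, Ctnnb1 and Mki67 were to be named in any case. Runx2 is not analysed here, because no probe set with its symbol alone was used. Symbols of cDNA clones and predicted genes were counted but not named. The rule gave 94 genes. For 43 of them at least 1 measured probe set had a signal below the filter on 1 array, where a log2 difference depends on the pseudocount and is no bound. A fold written as "at least" takes that signal as 71.3 in each probe set and averages the log2 ratios over the probe sets of the gene, which left 2 of the 43 under 2-fold, Lyz2 and Laptm5. Such a fold is a bound for the deposited scaling and the measured probe sets alone. Log2 ratios of control probe sets were taken without a pseudocount.

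The calling and list steps were tested on simulated arrays with 200 changed genes among 11138, with noise of the size of the SD between probe sets of 1 gene. The step called 94% of the genes set 3-fold higher, 96% of those set 3-fold lower and 100% of those set 6-fold either way. It called 1.03% of the unchanged genes and set 3 of 100 lists of unchanged genes apart. This noise leaves out any difference between cultures and was of the same size for bright and dim probe sets. The changed genes were drawn only from genes with control signals well above the filter. The recovery therefore does not cover dim genes, and the share of unchanged genes called need not hold for them.

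Alternatives planned before the data were examined were no pseudocount, a pseudocount at the median signal, no filter, a filter at the 75th percentile, centring on the median difference, quantile normalization, loess on the difference against mean log2 signal with a span of 0.3, the brightest probe set per gene, leaving out probe sets that match several transcripts, and a 3-fold threshold. The last 3 were not run for the single named genes. Of probe sets that match several transcripts, only those with IDs ending in _x_at or _s_at were left out. A further 3 were chosen after seeing the data, namely scaling on the hybridisation controls, scaling on the poly-A controls, and raising signals below the filter to it with no pseudocount. Both control scalings used the median log2 ratio of the control probe sets above the filter. The work used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.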

Results

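The data are 2 expression arrays, 1 of control-vector MOS-J cells and 1 of MOS-J cells carrying human DKK1. MOS-J is a mouse osteosarcoma line, and DKK1 is a secreted protein that blocks canonical Wnt signalling by binding the co-receptors LRP5 and LRP6. The comparison asks how the expression profile of these tumour cells differs when they carry human DKK1. Each group has 1 array, so no value below has a replicate error, and every difference is DKK1 minus control between these 2 arrays. The median signal over all probe sets was 62.6 on the control array and 78.6 on the DKK1 array. Over the measured probe sets, log2 signals of the 2 arrays correlated across probe sets with Pearson's r of 0.902. Probe sets are not independent replicates.

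Spike-in RNAs gave the technical agreement between the arrays, as log2 ratios of the signals with no pseudocount. The 18 hybridisation control probe sets, added after labelling, had a median log2 difference of −0.37 with a range of −0.59 to −0.24. Poly-A controls go through labelling, and the 20 of their 24 probe sets above the filter had a median of 0.64 with a range of 0.10 to 1.21. With the 4 dim ones included the median was 0.69 and the highest 5.39. The 3 Trpn probe sets were not counted among these controls. The 3' to 5' signal ratio, a sign of RNA integrity, was 0.823 for Gapdh on the control array and 0.759 on the DKK1 array. For Actb it was 1.61 and 1.25.

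The transgene is human, and mouse Dkk1 probe sets need not match it, so they check nothing about the labels. The signals of the 2 mouse Dkk1 probe sets were 13.0 and 10.97 on the control array against 42.5 and 2.01 on the DKK1 array, all below the filter of 71.3.

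Of 11058 measured genes, 1293 were at least 2-fold higher and 764 at least 2-fold lower in the DKK1 cells, 18.6% of all. At least 8-fold differences were found for 89 higher and 48 lower genes. Of the 773 called genes with at least 2 measured probe sets, 431 had every such probe set at least 2-fold different, and 15 genes that were 2-fold different on average were not called because their probe sets went both ways. Higher genes made up 62.9% of the calls. That split depended on the scaling, with 51.4% after median centring, 49.8% after quantile normalization, 51.5% after loess, 86.2% when scaled on the hybridisation controls and 15.1% when scaled on the poly-A controls. The median of all genes was 0.10 as deposited, 0.46 with the hybridisation controls and −0.52 with the poly-A controls, so which direction prevailed is not settled by these arrays. Under both of these scalings the 14 gene lists described below as standing apart stayed on their side of the random lists, while neural genes moved below theirs with the poly-A controls. A list and its random lists move nearly alike under such a scaling, so the side kept is no check on it.

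The highest genes in the DKK1 cells were secreted and cell surface proteins, a retinal-oxidising enzyme and a regulator of glucose uptake. All of the 10 but Ifitm1 had control signals below the filter of 71.3, so their log2 differences depend on the pseudocount and set no order among them. For these the fold is given as a lower bound on the deposited scaling. The dim signal was raised to 71.3, and the fold was averaged on the log scale over the measured probe sets of a gene. Omd, a keratan sulfate proteoglycan of mineralised tissue, had a signal of 44.8 in control and 7967 in DKK1 cells, a log2 difference of 7.02 and at least 112-fold. Igf2, an insulin-like growth factor, went from 13.9 to 4067 (7.06, at least 57.1-fold). Txnip, which binds thioredoxin and limits glucose uptake, differed by 6.85 (at least 50.8-fold). Aldh1a1, a retinaldehyde dehydrogenase, went from 6.67 to 2540 (6.78, at least 35.6-fold), and Colec12, a scavenger receptor, from 1.16 to 2469 (7.13, at least 34.6-fold). The Slit receptor gene Robo1 (6.28) was at least 29.8-fold higher, Abi3bp (6.75) at least 26.2-fold, the collagen gene Col8a2 (5.38) at least 19.1-fold and Otor (5.94) at least 17.9-fold. The interferon-induced Ifitm1 had both signals above the filter and differed by 5.17. Of these 10 highest genes only Abi3bp had more than 1 measured probe set. Among genes with several probe sets, Nrep was higher by 5.07 (SD 0.12 between 2 probe sets). The growth factor gene Igf1 was higher by 4.80 (SD 0.57, 4 probe sets, at least 13.4-fold). Fmod, a small leucine-rich proteoglycan that binds collagen, was higher by 4.76 (SD 0.99, 6 probe sets, at least 26.3-fold). Apod (4.14, SD 1.11 between 2 probe sets; at least 9.71-fold) and Prelp (3.94, at least 8.44-fold) were named by the same rule.

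Among the 10 lowest genes was Abcb1a, which encodes the drug efflux pump P-glycoprotein. Its signal was 6391 in control and 23.7 in DKK1 cells, a difference of −7.34 with an SD of 0.21 between 2 probe sets, or at least 89.2-fold. The mitochondrial folate enzyme gene Aldh1l2 (−4.73) had both signals above the filter. The other 8 of the lowest 10 had DKK1 signals below it, and their differences set no order. Car6, a secreted carbonic anhydrase (−5.97), was at least 73.9-fold lower and the cytokine gene Il33 (−5.04) at least 31.9-fold. Ch25h, cholesterol 25-hydroxylase (−5.54), was at least 22.1-fold lower and Dcn, the small proteoglycan decorin (−5.86), at least 18.9-fold. The bounds were 12.7-fold for the cystine transporter gene Slc7a11 (−4.67), 11.96-fold for Prag1 (−4.54), 10.3-fold for the amino acid transporter gene Slc7a2 (−5.01) and 9.46-fold for the protease gene Ctsk (−4.41). For Dcn, Slc7a2 and Prag1 the value rests on the 1 probe set above the filter. The values of Aldh1l2, Car6, Il33, Ch25h and Ctsk also rest on 1 measured probe set each. With the dim probe sets of Dcn, Slc7a2 and Prag1 included, their calls ended, at −2.26, −1.83 and −1.80. In each a dim probe set had the opposite sign, so the folds given for these genes are no bounds over all their probe sets. Among lower genes with several probe sets were Trib3 (−4.13), a pseudokinase gene induced by the stress factor ATF4, Ero1a (−3.65), an oxidase of disulfide bond formation, Gpr149 (−3.47, at least 3.10-fold), the branched-chain aminotransferase gene Bcat1 (−3.23, SD 1.93 between 3 probe sets; at least 6.76-fold) and Rnf128 (−3.23).

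**Figure D1:**
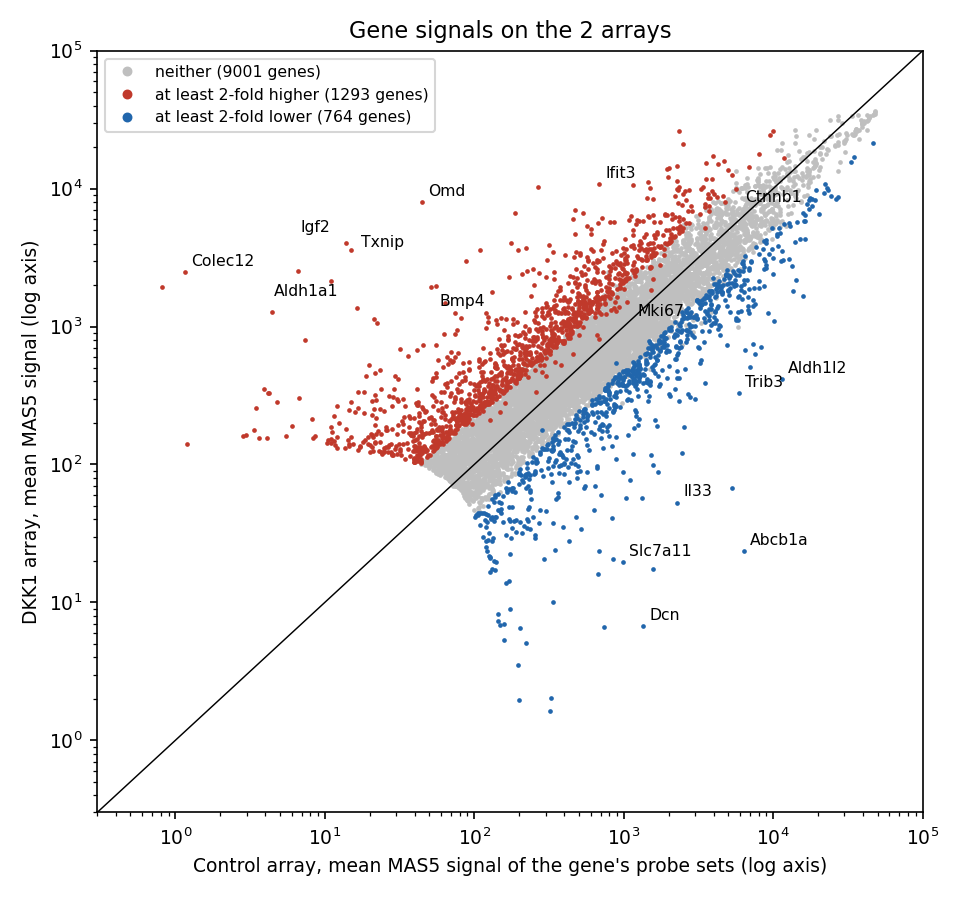
Mean MAS5 signal of each measured gene on the control array (x axis) and the DKK1 array (y axis), both log axes, with 1 point per gene, the 1293 higher genes in red, the 764 lower genes in blue and the other 9001 in grey. Colec12, Igf2, Txnip and Aldh1a1 lie far left of the diagonal with control signals under 15, and Abcb1a lies below it with signals of 6391 and 23.7.

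Of the 29 gene lists, 14 stood apart from matched random lists, 8 above and 6 below, and 15 did not. The strongest shift down was in genes of the integrated stress response and amino acid supply, which cells switch on through ATF4. Of 26 measured genes, 21 were lower and 1 was higher in the DKK1 cells. The median was −2.16, below all 10000 random lists, whose middle 95% ran from −0.31 to 0.32. The largest differences were those of Slc7a11 and Trib3 and of the transcription factor gene Atf3 (−3.78), with a signal of 1565 in control and 98.5 in DKK1 cells. Of these 26 genes, 5 are also on other lists.

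Endoplasmic reticulum chaperones and redox enzymes were lower too, with 13 of 21 measured genes lower, 0 higher and a median of −1.13. Ero1a led this list, followed by Herpud1 (−2.03), a gene of protein degradation at the endoplasmic reticulum, and Sdf2l1 (−1.95). Of 28 hypoxia and glycolysis genes, 12 were lower and 1 was higher, with a median of −0.97. They included Ero1a, the hexokinase gene Hk2 (−2.31) and the oxygen sensor gene Egln3 (−2.52, at least 3.57-fold). Both medians lay below all 10000 random lists. So did that of the oxidative stress and glutathione genes, at −0.67, where 11 of 34 were lower and 5 higher. Slc7a11 and the haem oxygenase gene Hmox1 (−3.27) were among the lower ones, while the carbonyl reductase gene Cbr3 was higher (3.87, at least 9.70-fold). Heat shock genes did not stand apart, with a median of −0.22 and percentile of 13.9. Hspb8 (−1.97) and Hspd1 (−1.36) were lower and Cryab (1.59) was higher, and the call of Hspd1 ended on the scaling by hybridisation controls (−0.98) and that of Cryab on that by poly-A controls (0.97).

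Genes induced by type I interferon formed the strongest shift up. Of 37 measured genes, 24 were higher and 0 lower in the DKK1 cells, with a median of 1.91 above all 10000 random lists, whose middle 95% ran from −0.24 to 0.29. Ifit3, an antiviral RNA-binding protein gene, had a signal of 687 in control and 10738 in DKK1 cells (3.93). Iigp1, an interferon-induced GTPase gene, differed by 3.55 and Dhx58, which encodes an RNA sensor, by 3.31. MHC class I antigen presentation genes had a median of 0.52, at percentile 99.3, with 2 of 16 called. These were the peptide trimming gene Erap1 (1.43) and the peptide loading gene Tapbp (1.35, at least 2.65-fold). When scaled on the poly-A controls both calls ended (0.83 and 0.76) and the list median was −0.12, still above its random range. Macrophage and leukocyte markers did not stand apart. Of 19 such genes on the array 7 were measured, with a median of 0.45, Lyz2 higher (2.29, with a signal of 136 in DKK1 cells) and Laptm5 lower (−1.10). Raising dim signals to the filter took both under 2-fold, at 0.93 and −0.67. The call of Laptm5 also ended with the larger pseudocount (−0.68), without the filter (−0.15) and with hybridisation scaling (−0.80). The median of the leukocyte markers was −0.44 with quantile normalization and −0.72 with poly-A scaling, both within the random range. Chemokine, cytokine and NF-kB genes did not stand apart either, with 3 of 27 higher, 8 lower and a median of −0.08. Il33, Il6 (−2.46) and the cyclooxygenase gene Ptgs2 (−2.33) were among the lower ones.

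**Figure D2:**
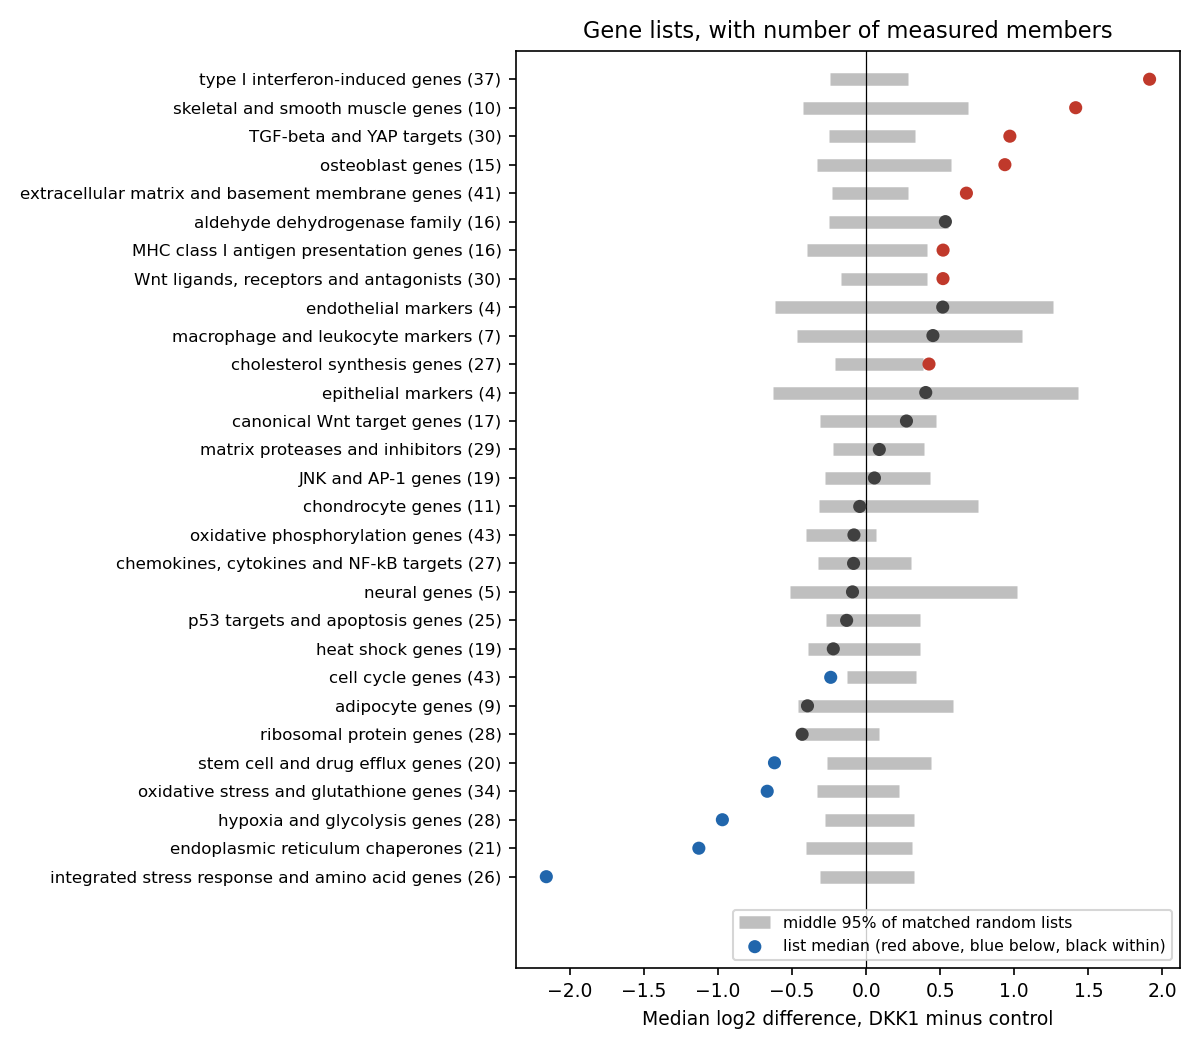
Median log2 difference of each of the 29 gene lists (x axis; points, with the number of measured genes in the label) and the middle 95% of 10000 matched random lists (grey bars). The 8 lists above the random range are red, the 6 below are blue and the 15 within are black, and on the scaling by poly-A controls the MHC class I, Wnt ligand and cholesterol medians fall below 0, as the cell cycle median rises above 0 on that by hybridisation controls.

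Lists of matrix, bone and contractile genes lay above random lists in the DKK1 cells, with part of their members not called. Of 41 extracellular matrix and basement membrane genes, 13 were higher and 2 lower, with a median of 0.68 above all 10000 random lists. Fmod and the basement membrane gene Nid2 (3.98) were higher, and Dcn was lower. Targets of TGF-beta and YAP had 15 of 30 genes higher, 0 lower and a median of 0.97, above all random lists. They were led by the matrix gene Thbs1 (3.71), the inhibitory Smad gene Smad6 (3.32) and Ltbp2 (3.18), which encodes a microfibril protein. Of 15 osteoblast genes, 7 were higher and 1 was lower, with a median of 0.94 at percentile 99.9. Omd, the bone morphogenetic protein gene Bmp4 (4.83; signals of 51.7 and 1924) and Tnfrsf11b (3.68), which encodes the osteoclast inhibitor osteoprotegerin, were among the higher ones. The 1 lower gene, Phex, had signals of 200 in control and 1.97 in DKK1 cells. Among the 7 not called were Col1a1 (0.79), Sp7 (0.36), Alpl (0.27) and Col1a2 (0.05). Phex and these uncalled genes were added outside the naming rule. Runx2, a regulator of bone formation, is not analysed here. Of 10 skeletal and smooth muscle genes, 6 were higher and 1 was lower, with a median of 1.41 above all random lists. The genes named were those of smooth muscle contraction, Myl9 (3.31), Tagln (3.08, at least 3.46-fold) and Acta2 (2.58, at least 3.67-fold). The osteoblast and muscle lists no longer stood apart without the filter on dim probe sets, with medians of 0.35 and 0.27. Each shares 2 of its measured genes with other lists.

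Matrix proteases and their inhibitors did not stand apart, with a median of 0.09. Ctsk and Mmp23 (−2.55) were lower and Timp2, an inhibitor of metalloproteinases, was higher (2.02, SD 0.86 between 5 probe sets, at least 3.91-fold). Chondrocyte genes had a median of −0.04 at percentile 15.2, with Sox5 (1.50, at least 2.08-fold) and Col11a1 (1.27) higher and Runx3 (−1.12) lower. Runx3 turned to 0.34 when its dim probe set was included, and the call of Sox5 ended without the filter (0.80) and that of Col11a1 with the stricter filter. Both also ended with poly-A scaling (0.70 and 0.66), and that of Runx3 with hybridisation scaling (−0.75).

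The Wnt pathway was examined through 2 lists. Canonical Wnt target genes did not stand apart. Of 17 measured, 4 were higher and 2 lower, with a median of 0.27 at percentile 82.1. Its direction was not stable, with a median of −0.13 without the filter and −0.31 on the scaling by poly-A controls, both within the random range. Axin2, a feedback inhibitor used as a readout of canonical signalling, had signals of 64.5 in control and 155 in DKK1 cells, a difference of 1.08. Its call ended under 5 of the alternatives, where the difference was 0.54 to 0.96. Id2 was higher (2.04, at least 3.81-fold), and Ccn4 (−1.65) and Myc (−1.53) were lower. Ctnnb1, which encodes beta-catenin, was not called (0.42, SD 0.24 between 3 probe sets). Wnt ligands, receptors and antagonists had a median of 0.52 at percentile 99.7, with 9 of 30 genes higher and 2 lower. Dkk3, a relative of Dkk1 (3.29), the Wnt enhancer gene Rspo2 (2.81) and the receptor gene Fzd1 (2.31) were the highest, and the call of Rspo2 ended with quantile normalization (1.29) and with poly-A scaling (0.84), where a dimmer probe set of the opposite sign passed the filter. Without the filter the median was 0.22 at percentile 93.7, and on the scaling by poly-A controls it was −0.15, still above its random range. Genes of the JNK and AP-1 pathway did not stand apart, with a median of 0.06. Atf3 was lower, and Dusp1 (1.81) and Fos (1.79) were higher.

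Aldehyde dehydrogenases, used as markers of drug resistance and stem-like tumour cells, had 4 of 16 genes higher and 2 lower. The median was 0.53 at percentile 96.9, within the random range, and it moved above that range under 6 of the alternatives. The genes named went in both directions, with Aldh1a1 and Aldh1a7 (2.68, at least 4.03-fold) higher and Aldh1l2 lower (signals of 11426 and 415). Stem cell and drug efflux genes stood apart below, with 8 of 20 lower, 2 higher and a median of −0.62. Abcb1a and the transporter gene Abcc4 (−3.54) were lower, and the surface marker gene Cd24a was higher (3.62, SD 0.14 between 3 probe sets). Of these 20 genes, 5 are also on other lists.

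**Figure D3:**
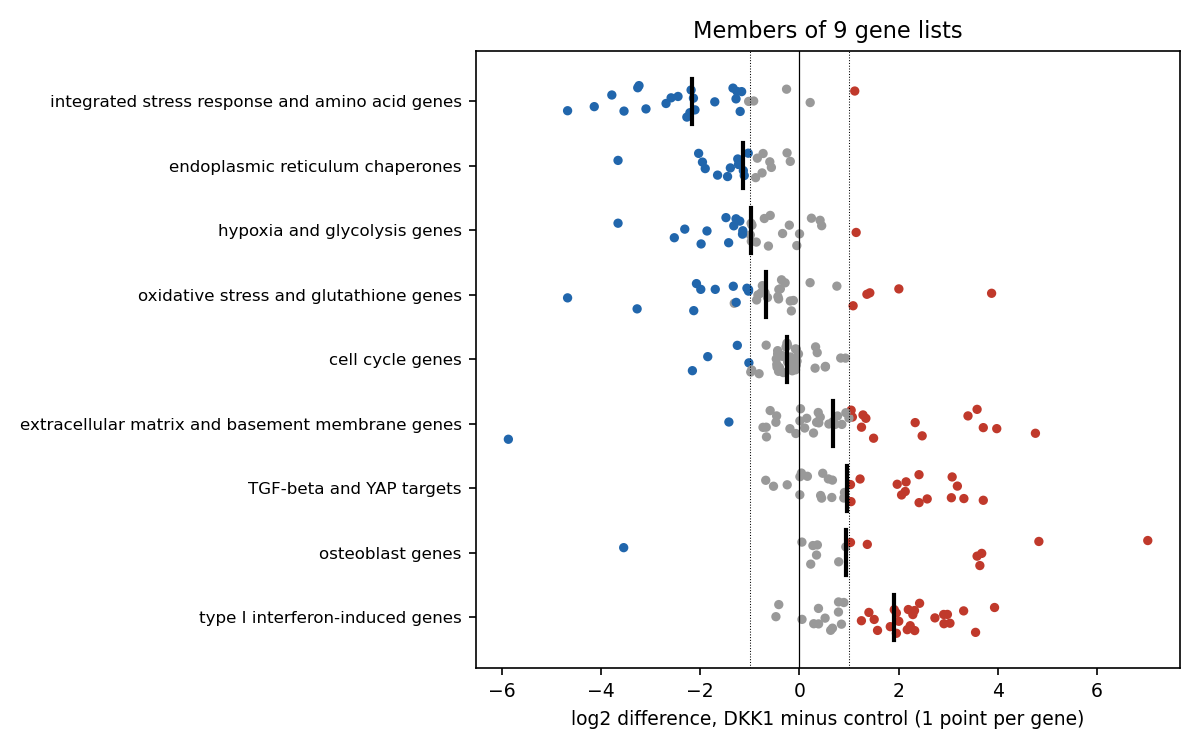
Log2 difference, DKK1 minus control, of each measured gene (points) in 9 of the 29 lists, with higher genes red, lower genes blue, uncalled genes grey, a black bar at the list median and dotted lines at 2-fold. Of the stress response genes 21 of 26 lie to the left as lower, and of the interferon-induced genes 24 of 37 lie to the right as higher, while the cell cycle genes gather near 0 with 4 of 43 lower.

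Cell cycle genes lay slightly below random lists, with a median of −0.24 at percentile 0.26, where the middle 95% of random lists ran from −0.13 to 0.34. Of 43 genes, 4 were lower and 0 higher, among them the replication genes Cdt1 (−2.16) and Mcm2 (−1.85) and the mitosis gene Cdc20 (−1.25). The call of Cdt1 ended without the filter (−1.27), and that of Cdc20 on the scaling by hybridisation controls (−0.89). Mki67, a marker of cycling cells, was not called, at −0.06 with signals of 1119 and 1072. Scaled on the hybridisation controls the list median was 0.10, still below its random range. Targets of p53 and apoptosis genes did not stand apart, with 3 of 25 higher, 7 lower and a median of −0.13. Plk2 (−2.89), the growth arrest gene Gadd45a (−2.85) and the death receptor gene Tnfrsf10b (−1.89, at least 2.68-fold) were among the lower ones.

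Cholesterol and fatty acid synthesis genes had 7 of 27 higher, 0 lower and a median of 0.42 at percentile 98.7. The desaturase genes Fads2 (1.96, at least 3.56-fold) and Fads1 (1.49) and the sterol synthesis gene Hmgcs1 (1.61, at least 2.68-fold) were the highest. Without the filter the median was 0.32 at percentile 93.1, and it was −0.20 on the scaling by poly-A controls, still above its random range, where the calls of Fads1 (0.88) and Hmgcs1 (0.89) ended. Oxidative phosphorylation genes did not stand apart, with a median of −0.08 and 1 of 43 called, the cytochrome c gene Cycs (−1.20), whose call ended without the filter (−0.99) and on the scaling by hybridisation controls (−0.83). Ribosomal protein genes had a median of −0.43 at percentile 3.75, with 0 of 28 called. Of the 46 ribosomal protein genes listed 29 were matched on the array, which leaves that list, like the osteoblast list with 24 of 32 and the MHC class I list with 16 of 22, covered in part.

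Endothelial, epithelial, adipocyte and neural lists did not stand apart, unlike the muscle list. Endothelial and epithelial markers had 4 measured genes each and 0 called, with medians of 0.52 and 0.40. Of 9 adipocyte genes 2 were higher and 3 lower, with a median of −0.40. The sign of that median was not stable. It was 0.22 without the filter and 0.22 with the 75th percentile filter, both within the random range. The regulator gene Pparg was higher (2.47), and Lpl (−3.34, at least 8.82-fold) and Plin2 (−1.65) were lower. Of 5 neural genes 2 were higher and 1 was lower, with a median of −0.09. Map2 (2.61, at least 5.68-fold) and Sox10 (1.71, at least 3.37-fold) were higher and L1cam (−1.28) was lower. Without the filter Sox10 turned to −0.16 and the calls of Map2 and L1cam ended. That of L1cam also ended with the larger pseudocount (−0.94) and with hybridisation scaling (−0.95).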

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

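The count of probe sets with no single symbol was chosen after the main values were seen, while the control probe sets were part of the plan. Among 3139 measured probe sets with no single gene symbol here, 649 were at least 2-fold higher in the DKK1 cells and 137 at least 2-fold lower. Among the 19360 measured probe sets with 1 symbol the counts were 2350 and 1453. These probe sets, 571 of which have several symbols, enter no count of genes in the report.

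The poly-A control probe sets above the filter drew attention because their median log2 difference of 0.64 lies outside the main measurement and is opposite in sign to that of the hybridisation controls, −0.37. The range of these 20 poly-A probe sets was 0.10 to 1.21, and with the 4 below the filter included the highest was 5.39.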

How the results depend on the processing

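The scalings on control probe sets and the raising of dim signals were chosen after seeing the data, and the others before. The count of called genes, 2057, was 1337 (711 higher) with the 75th percentile filter and 823 (534 higher, 289 lower) at 3-fold. Scaled on the hybridisation controls 2389 genes were higher and 381 lower. Scaled on the poly-A controls 472 were higher and 2663 lower, 3135 in all. Both control scalings add nearly the same shift to every gene, which by construction moves genes across the threshold. Of 344 list values over these settings, 327 stayed on the same side of the random range. The median of 34 of these had the other sign, 30 of them within the random range and spread over 14 lists. Without the filter the lists of Wnt ligands and receptors (0.22), osteoblast genes (0.35), cholesterol synthesis (0.32) and muscle genes (0.27) no longer stood apart, and endothelial markers did (−0.22). The cause was not tested. With poly-A scaling the medians of Wnt ligands and receptors (−0.15), MHC class I (−0.12) and cholesterol synthesis (−0.20) changed sign and stayed above their random ranges, and neural genes moved below (−1.11). With hybridisation scaling the cell cycle median was 0.10. Aldehyde dehydrogenases moved above the random range with the larger pseudocount (0.48), quantile normalization (0.45), loess (0.43) and the brightest probe set (0.61). They also did so without probe sets with IDs ending in _x_at or _s_at (0.56) and with raised signals (0.56). Targets of p53 moved below it with quantile normalization (−0.38) and loess (−0.35), adipocyte genes with loess (−0.54), and ribosomal protein genes with the 75th percentile filter (−0.43) and the brightest probe set (−0.43). Of 910 values of 93 named genes, 874 kept their call or lack of one and 34, in 21 genes, lost the call with the direction kept. Without the filter Runx3 (0.34) and Sox10 (−0.16) reversed, because probe sets under the filter had the opposite sign. Dim signals limit the genes whose signal lies below the filter on 1 array. No paired analysis was possible because each group has 1 array, and leaving out a replicate was not possible for the same reason.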

Other observations

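The families, the chromosome parts, the leukocyte values, the scalings on control probe sets and the bounds of each test were chosen after the main values had been seen, as were the genes named here, which fall outside the naming rule. Median centring, quantile normalization, loess and leaving out probe sets with IDs ending in _x_at or _s_at were planned as alternatives for the gene lists. Aminoacyl-tRNA synthetases, which load amino acids onto tRNAs, were lower in the DKK1 cells, as were the amino acid genes of the report. Of 16 genes matched by symbol and measured, 12 were lower and 0 higher, with a median log2 difference of −1.44. Gars (−2.28; signals of 13413 and 2744) and Aars (−2.12) were the lowest, and Qars alone was above 0 as deposited (0.52). Of 11 genes whose symbols start with Utp, known for ribosome assembly, 5 were lower and 0 higher, with a median of −0.91. Of 8 Nop genes 3 were lower, with a median of −0.91, Nop56 (−2.16) among them, and of 10 Nol genes 1 was lower and 1 higher, with a median of −0.46, also below random lists. The synthetase, Utp and Nop medians stayed below 0 under all 5 other scalings.

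Several gene clusters and signalling families were higher. They come from a look at 366 groups of at least 5 measured genes that share the letters before the first digit of their symbols, of which 26 lay above and 21 below matched random lists where 18.3 would by chance. All 5 Gbp genes, interferon-induced GTPases partly on the interferon list, were higher, with a median of 2.85. Of 9 clustered protocadherins (Pcdhb) 7 were higher, with a median of 1.54, and of 7 Hoxc homeobox genes 5, with a median of 1.18, Hoxc8 the highest (2.31). Of 5 genes starting with Bmp, 3 were higher (Bmp2, Bmp4 and Bmp7), with a median of 2.30. Of 5 insulin-like growth factor binding proteins 4 were higher, with a median of 1.62, Igfbp3 the highest (3.23). The medians of these 5 families stayed above 0 under all 5 other scalings. Members of the Pcdhb and Gbp families are close in sequence, so their probe sets need not be independent.

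The lower level of stress response, chaperone and glycolysis genes was weighed against technical causes. Over 5 other scalings the highest of the 3 list medians was −0.61 and all 3 lists stayed below random lists. Median centring and both control scalings shift nearly all genes alike, so under them the place among random lists could hardly change. The sign of the medians could change and did not, and under quantile normalization and loess the lists stayed below random lists. These values argue against the scaling as the whole cause. Without probe sets with IDs ending in _x_at or _s_at the stress list median was −2.21, which argues against these probe sets as the cause. Cross-hybridisation of the remaining probe sets was not tested. With 1 culture per line, medium exhaustion or density at harvest and an effect of DKK1 cannot be told apart, and with 1 array per line no value here decides between them.

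The interferon-induced genes kept a median of at least 1.28 over the same 5 scalings. They stayed above random lists in each, which only quantile normalization and loess could readily have changed. These values argue against the scaling as the whole cause. Leukocytes in the sample stay open after several tests were tried. The 7 measured leukocyte markers had a median of 0.45 and went both ways, with 3 below 0, and the others of the 19 on the array lay under the filter. The sign of the list median was not stable, at −0.44 with quantile normalization and −0.72 with poly-A scaling. The markers were dim in the DKK1 cells, with a median signal of 53.4 over the highest probe set of each, and no marker probe set gained more than 151. A bound on the marker signals that pure leukocytes could have depended on the share assumed. It had a median of 235 at the share of 22.7% that Ifit3 alone would need at least, the largest share among the higher interferon genes. At the median share of 3.66% over these genes the median bound was 1458, but that share falls short for the genes that need more. Both shares take a gene's signal in leukocytes as the highest on the DKK1 array, 45032. The 75th percentile of the array was 436, between these bounds, and no signals of leukocytes were at hand to set a level. The protocol describes cell sorting on a fluorescent label, which would remove unlabelled leukocytes, but whether the profiled cells were sorted is not given. Vector delivery or selection of the line may raise interferon-induced genes without DKK1, and with 1 line per arm this and an effect of DKK1 cannot be told apart.

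Genes of whole chromosome parts were shifted together. Each of 20 chromosomes was divided into 6 parts of equal gene number. Of 120 parts, 40 stood apart from matched random lists (19 above, 21 below) where 6 would by chance. After loess with the 75th percentile filter, 28 of the 40, matched by their number along the chromosome, did so the same way. The parts were drawn anew there from the genes left, so their limits and genes differ. Of the 20 whole chromosomes, 19 had the highest median as deposited, 0.50 over 405 genes with 75.6% above 0. That median was −0.10 on the scaling by poly-A controls but still 0.41 above all genes there. For chromosome 19 alone, picked here as the highest, a trend with brightness is argued against by a median of 0.37 after loess with the stricter filter. That median lay above its random range. Neighbouring members of 1 family, where they share the first 4 letters of their symbols (the stem), are argued against by medians of 15 neighbouring genes. Their SD was 0.283 with 1 gene per symbol stem, 0.287 with all genes and at most 0.228 in 1000 shuffles. Families with unlike symbols were not thinned. The shuffles moved genes across chromosomes, so this SD also holds shifts of whole chromosomes. The shifts also changed within chromosomes. On chromosome 14 the median was 0.15 and 0.12 in parts 1 and 2 and −0.67 in part 6, and on chromosome 2 it was −0.06 in part 3, 0.50 in part 5 and 0.48 in part 6 (−0.11 and −0.15 on the scaling by poly-A controls). A different copy number of whole chromosomes alone is argued against by the SD of part medians around the median of their own chromosome, 0.135, against at most 0.110 in 1000 shuffles of genes within chromosomes. Different copy number of chromosome segments and regional regulation were not tested, copy number was not measured, and a trend with GC content was not examined here.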
